A study of Homo sapiens with 4 samples.

How the data were processed

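Poly-A RNA of human K562 cells, an established line of chronic myeloid leukaemia that carries the BCR-ABL fusion, was measured by RNA-seq in 4 libraries. The groups, taken from the sample labels, were parental cells, an imatinib-resistant derivative, cells given vesicles named R-Exo and cells given vesicles named S-Exo. Imatinib is an inhibitor of the BCR-ABL kinase. R-Exo and S-Exo were read as exosomes, small vesicles that cells release, of resistant and of sensitive cells, and the exposure was 48 h, per the labels' protocols. Each group had 1 library, so no difference had a replicate check, and no p-value, standard error or count of significant genes was computed. Libraries were built from 1 µg of RNA with a NEBNext Ultra kit and selected at about 240 bp, per the labels' protocols.

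The authors deposited 1 table of FPKM values (fragments scaled to the length of the gene model and to the mapped fragments of the library) with a column for each library, and the unit was taken from the table's name. The name also states that the table holds differentially expressed genes, and the rule that selected them is not given in the sources used here. Of its 3200 rows, 3069 (95.91%) had a 2-fold or larger ratio, after 0.01 was added to both values, in one or more of the 6 library pairs. Every share and median below therefore describes genes that the authors had already selected for differing, not the whole transcriptome. TopHat2, Picard, GATK and SAMtools 0.1.18 are named in the submitters' processing notes without a role. The genome build, the annotation and the counting tool are not given in the sources used here. Of the rows, 2288 had an Ensembl gene identifier and 912 had a running number and no gene name. All 2288 identifiers were found in GENCODE release 29, 2283 with the same symbol, and 2285 of them are protein-coding there. The other 3 are polymorphic pseudogenes. Positions and overlaps of gene models came from that release (GRCh38), matched by identifier.

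The depth is unknown, so no interval was put on an expression value. Low values were examined for steps of whole reads: among 195 genes between 0 and 0.15 FPKM in both the parental and the S-Exo library, the log2 ratios took 188 distinct values at 3 decimals, so no step could be read. A value of 0 is given as "listed at 0", and no fold was computed against it.

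For each gene the difference between 2 libraries was log2 of (FPKM + 1) in one minus the same in the other. This scale understates the difference of genes with low values. Genes with at least 1 FPKM in one or both libraries were compared, and those with an absolute log2 difference of at least 1 were counted as higher or lower. Plain ratios of FPKM are given as folds where both values were above 0. The planned comparisons were resistant against parental, R-Exo against S-Exo (the control that the series description names), R-Exo against parental and S-Exo against parental. The resemblance of R-Exo to resistant was described by the correlation across genes of the resistant/parental and R-Exo/S-Exo differences, which share no library, and by the overlap of the genes counted. The level of resistant-specific genes (at least 5 FPKM in resistant and at most 0.1 in parental) was also taken. Genes are not independent replicates, and these correlations describe 4 libraries.

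The text names the 10 highest and 10 lowest genes of the 2 main comparisons and the 5 highest and 5 lowest of the other 2, among genes with a symbol and at least 5 FPKM in one or both libraries. It also names up to 4 members of each gene list with the largest absolute difference, and ABCB1, ABCG2, BCR, ABL1 and LYN wherever they were listed. Of those last 5, only ABCB1 was in the table. Some genes that this rule names are not reported here. The 28 gene lists, this rule, the comparisons and the alternatives were fixed before the data were examined. A list with at least 5 compared members was given a median, and the percentile of that median among 10000 random lists of the same size matched on mean expression in 10 bins. That percentile describes these libraries and is not a p-value. In every list most members were absent from the table, so counts and medians describe the listed members and not the whole group.

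Added after the values had been seen were the comparison of R-Exo with resistant, the parental-specific genes, the share of the parental-to-resistant distance, the counts in windows of 15 neighbouring coding genes with 1000 shuffles of the values, the block around ABCB1, the zinc finger genes, the chromosomes and the overlapping gene models. The alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, re-scaling to a median difference of 0, quantile normalization over the listed genes, the parental library as control of R-Exo, and other limits for resistant-specific genes. Exact binomial 95% intervals are given for shares of genes. They treat genes as independent draws, which genes of 1 overlapping locus are not, and they cover no variation between libraries. The steps were tested on simulated data of 3200 genes, in which 100% of 200 genes with a 4-fold difference were counted and 0 unchanged genes were. The simulated noise was smaller than the spread of the S-Exo/parental differences, and only genes with at least 5 FPKM in parental were changed. That outcome checks the counting steps and gives no error rate for these libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.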

Results

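RNA of K562 cells was measured in 4 libraries, 1 each of parental cells, imatinib-resistant cells, cells given R-Exo vesicles for 48 h and cells given S-Exo vesicles for 48 h. The table held 3200 genes that the authors had selected as differentially expressed. The FPKM of these genes summed to 21422.6 in parental, 23728.5 in resistant, 23833.8 in R-Exo and 21405 in S-Exo. The median was 0.946, 1.21, 1.10 and 1.01 FPKM in the same order, and 154, 113, 111 and 161 genes were listed at 0. The highest value was that of MT-ND3, a mitochondrially encoded subunit of complex I, in parental (877 FPKM) and in S-Exo (1060 FPKM). In resistant (1101 FPKM) and in R-Exo (1253 FPKM) it was that of HBZ, the embryonic zeta-globin gene. HBZ and MT-ND3 are named here as the highest values, after these had been seen. Across the 3200 genes, Pearson's r of log2 (FPKM + 1) was 0.977 between parental and S-Exo and 0.974 between resistant and R-Exo. The other 4 pairs lay between 0.729 and 0.736. With 1 library per group, none of the differences below could be set against a spread between replicates.

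The comparison of resistant with parental cells describes the imatinib-resistant line. ABCB1, which encodes the drug efflux pump P-glycoprotein, had 778 FPKM in resistant and 0.222 in parental cells, a log2 difference of 9.32. Among the other genes that the fixed rule names was CROT (111 FPKM in resistant, listed at 0 in parental), which encodes a peroxisomal carnitine acyltransferase. Further ones were SSX1, a cancer-testis antigen gene (60.5 against 0.276 FPKM), KIAA1324L (207 against 4.94), LCP1, which encodes the actin-bundling protein L-plastin (55.5 against 0.654), and PRKCA, which encodes protein kinase C alpha (172 against 5.79). The highest genes also held CA2, a carbonic anhydrase gene of red cells (25.2 against 0.0881), SLC25A40, a mitochondrial carrier gene (254 against 9.64), and FKBP10 (22.3, listed at 0 in parental). ABCB1, CROT, KIAA1324L and SLC25A40 lie on chromosome 7.

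The lowest genes in resistant cells were SSX2B and SSX2, with 54.1 and 45.7 FPKM in parental and both listed at 0 in resistant. These near-identical paralogs share reads, so the value of each one is uncertain. SOHLH2, which encodes a germ-cell transcription factor, had 27.9 FPKM in parental and 0.327 in resistant. CBR1, which encodes a carbonyl reductase, had 18.4 FPKM in parental and was listed at 0 in resistant. NMI was 17.6-fold lower in resistant (32.9 against 1.86 FPKM), and SELENOP, which encodes a selenium transport protein, was 14.6-fold lower (35.6 against 2.43). The others were RPL17-C18orf32, a readthrough model that overlaps other genes (8.48 in parental, listed at 0 in resistant), DCAF4L2 (9.10 against 0.135), NLRP2 (7.80, listed at 0 in resistant) and EREG, which encodes the growth factor epiregulin (8.06 against 0.0321).

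The listed erythroid and globin genes, 11 of the 46 in that list, were mostly higher in resistant cells. Of the 11 listed and compared, 8 were counted as higher and 0 as lower, and their median log2 difference of 2.09 lay at percentile 99.99 of random lists. The examples were CA2, GYPB, which encodes a red-cell surface protein (89.9 against 18.4 FPKM), and EPB42, a red-cell membrane protein gene (4.92 against 0.278). GYPB has close paralogs and can share reads with them. Replication-dependent histone genes had 6 of 9 members higher and 0 lower (median 1.10, percentile 94.9), with HIST2H3D at 5.32 against 1.12 FPKM and HIST2H2BE at 76.2 against 28.7. Most transcripts of these genes lack a poly-A tail, so their values in these poly-A libraries are uncertain in every comparison. With the median difference of all compared genes set to 0 (re-scaled), 1 of the 9 histone genes was higher (median 0.68). Of 5 heat shock genes, 4 were higher and 0 lower (median 1.11, percentile 90.44). HSPA1A had 275 against 126 FPKM, HSPA1B 241 against 113 and SERPINH1 73.4 against 33.5. HSPA1A and HSPA1B are near-identical paralogs that can share reads, so they are not independent observations. Re-scaled, 0 of the 5 heat shock genes were higher (median 0.69). Cancer-testis antigen genes had 5 of 15 members higher and 1, SSX2, lower (median 0.94, percentile 88.76), with MAGEA1 at 25.4 against 0.188 FPKM and MAGEC2 at 59.5 against 20.3. Re-scaled, 4 were higher and 1 lower (median 0.52), while 7 erythroid and globin genes were higher and 1 lower (median 1.67).

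The listed interferon-stimulated genes, 18 of the 48 in that list, were among the lower groups. Of 9 compared, 4 were lower and 1, IFI27L2, was higher, and the median of -0.97 lay at percentile 0.65; ISG15 had 4.82 FPKM in resistant against 13.6 in parental and PARP9 0.318 against 2.20. Only 5 of the 78 ribosomal protein genes in that list were in the table. Of these 5, 4 were lower and 0 higher (median -1.23, percentile 0.81), such as RPL35A (186 against 442 FPKM) and RPS25 (368 against 863). Of 6 amino acid response and unfolded protein genes, 3 were lower and 1 higher (median -1.01, percentile 4.79). PHGDH and PSAT1, which encode enzymes of serine synthesis, had 7.23 against 25.7 and 18.8 against 47.9 FPKM, while GDF15 had 54.9 against 21.5. In the list of exosome biogenesis and tetraspanin genes, 3 of 5 were lower and 2 higher (median -1.11, percentile 3.73). The tetraspanin genes CD9 (0.267 against 3.13 FPKM) and CD53 (29.4 against 81.6) were lower, and MFGE8 (48.4 against 17.1), which encodes lactadherin, was higher.

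Most of the other lists held members on both sides. TGF-beta, BMP and Wnt genes had 4 of 8 higher and 1 lower (median 0.92, percentile 88.89), with the transcription factor gene LEF1 at 11.3 against 0.115 FPKM and the Wnt receptor gene FZD4 at 1.86 against 7.47. FZD1, among the higher, lies in the run of higher genes around ABCB1 on chromosome 7 that is described below. ERK feedback and immediate early genes had 3 of 10 higher and 1 lower (median 0.76, percentile 78.85), with FOS at 9.19 against 1.54 FPKM. For the kinases of the BCR-ABL and bypass list, 2 of 9 were higher and 2 lower (median -0.19, percentile 34.4); the tyrosine kinase gene SYK had 5.12 FPKM in parental and was listed at 0 in resistant, and MERTK had 2.14 against 0.430. Drug metabolism and glutathione genes had 2 of 8 higher and 3 lower (median -0.19, percentile 31.35), with CYP3A5 at 5.49 against 0.852 FPKM and AKR1C1 at 7.25 against 26.1. The median of this list was -1.04 over genes with at least 5 FPKM. Megakaryocyte and platelet genes had 2 of 6 higher and 2 lower, with a median of -0.08 and a mean of 0.12, and ITGA2B, a platelet integrin gene, had 18.5 against 2.06 FPKM. Extracellular matrix, adhesion and mesenchymal genes had 3 of 8 higher and 3 lower, with a median of -0.24 and a mean of 0.04; SPARC had 23.4 against 4.90 FPKM and S100A6 4.50 against 22.0. The BCL2 family and cell death list had 2 of 6 higher and 3 lower (median -0.20), with the death receptor gene FAS at 0.0179 FPKM in resistant against 1.61. The NF-kB and cytokine list had 1 of 7 higher and 2 lower (median -0.29), and the glycolysis and hypoxia list 0 of 7 higher and 1, DDIT4, lower (median -0.60).

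Lists with fewer than 5 compared members were given no median. Both listed ABC and SLC transporter genes were higher, namely ABCB1 and ABCB4 (2.76 FPKM, listed at 0 in parental). ABCB4 is a paralog beside ABCB1 and can share reads with it, so its value is uncertain. Of 4 leukaemic stem and progenitor genes, CD44 was higher (7.80 against 1.66 FPKM) and ALDH1A1, an aldehyde dehydrogenase gene, was lower (2.45 against 22.8). The lymphoid genes CD3D (8.85 against 0.410) and CD22 (4.22 against 0.563) and the myeloid gene CD33 (4.71 against 0.543) were higher. Of 4 cholesterol and fatty acid synthesis genes 3 were higher and 0 lower, with CYP51A1 3.42-fold higher at 71.8 FPKM. CYP51A1 ends the run of higher genes around ABCB1 on chromosome 7 that is described below. The other higher members, MVD (33.9 against 15.8 FPKM) and FDFT1 (112 against 53.3), lay just past the limit. Of 4 autophagy and lysosome genes 2 were higher and 0 lower, with WIPI1 at 15.6 against 3.84. In the MHC list, 2 of 3 compared genes were lower and 0 higher. The lower ones were PSMB9 (1.39 FPKM in parental, listed at 0 in resistant) and TAP1 (0.457 against 1.94). ULBP2 was the other compared member, so no HLA gene was compared. Of 3 cell cycle genes, CDK6 was higher (42.6 against 6.65 FPKM) and 0 were lower. None of the compared members of the STAT5 target list (3 genes), the mast cell, basophil and eosinophil list (2) and the mitochondrially encoded list (1) passed the size limit. PIM1, a STAT5 target, had 46.0 FPKM in resistant against 92.4 in parental.

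In all, 2151 genes were compared between resistant and parental, of which 602 were higher and 390 lower. The median difference over the compared genes was 0.42, and when it was set to 0 the counts were 276 higher and 755 lower, so the higher share was 60.7% as deposited and 26.8% re-scaled. It was 45.2% after quantile normalization. Re-scaling moved each of the 17 list medians of this comparison by that shift. TGF-beta, BMP and Wnt genes then had 1 member higher and 3 lower (median 0.50), ERK feedback genes 2 and 2 (median 0.34), the kinase list 1 and 4 (median -0.61), drug metabolism genes 1 and 4 (median -0.61) and BCL2 family genes 0 and 3 (median -0.62). Extracellular matrix genes had 2 higher and 4 lower (median -0.66), megakaryocyte genes 2 and 3 (median -0.50), NF-kB genes 0 and 2 (median -0.71), and glycolysis and hypoxia genes 0 and 4 (median -1.02). Interferon-stimulated genes had 0 higher and 5 lower (median -1.39), ribosomal protein genes 0 and 5 (median -1.65), amino acid response genes 0 and 5 (median -1.43), and exosome and tetraspanin genes 1 and 3 (median -1.53). Of the lists without a median, cholesterol synthesis and autophagy genes had 1 higher each and 0 lower, and STAT5 targets 2 lower. The mast cell, stem and progenitor, mitochondrially encoded and cell cycle lists each had 1 more member lower.

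R-Exo was compared with S-Exo to set vesicles of resistant cells against vesicles of sensitive cells. The R-Exo library may instead hold RNA of resistant-line cells, as weighed below, so these differences cannot be credited to vesicles. ABCB1 was again the highest gene, with 677 FPKM in R-Exo and 0.0985 in S-Exo, a log2 difference of 9.27. Others among the highest were CROT (90.3 FPKM, listed at 0 in S-Exo), SSX1 (70.7 against 0.232), KIAA1324L (249 against 4.77) and LCP1 (56.0 against 0.510). Further ones were TMEM243 (63.0 against 1.21), DBF4, which encodes a regulator of the CDC7 replication kinase (975 against 40.7), FKBP10 (19.7, listed at 0 in S-Exo) and CA8 (20.7 against 0.143). The lowest gene was SENP3-EIF4A1, a readthrough model that overlaps SENP3 and EIF4A1, with 0.489 FPKM in R-Exo and 165 in S-Exo. It had 3.71 FPKM in parental and 0.237 in resistant, so this difference rests mostly on the high S-Exo value. It was followed by SSX2 and SSX2B (44.8 and 44.0 FPKM in S-Exo, both listed at 0 in R-Exo), CBR1 (18.4, listed at 0 in R-Exo), SOHLH2 (0.466, 53.7-fold lower) and NMI (1.33 against 31.9). ALDH1A1 (1.24 against 23.3), SELENOP (2.09 against 31.1), DCAF4L2 (0.0300 against 9.32) and APOE (0.459 against 12.6), which encodes a lipid transport protein, completed the 10 lowest.

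The gene lists in R-Exo against S-Exo gave the following counts. Erythroid and globin genes had 8 of 11 members higher and 1 lower (median 1.83, percentile 100), with CA2 at 20.3 against 0.160 FPKM and GYPB at 91.7 against 16.2. Cancer-testis antigen genes had 10 of 14 higher and 2 lower (median 1.19, percentile 99.67), with MAGEA1 at 22.0 against 0.721. Among the higher were GAGE12J (68.0 FPKM, against 29.3 in S-Exo and 48.8 in parental) and CSAG3 (24.6, against 10.2 and 14.7). Neither passed the limit in R-Exo against parental, so their count here rests partly on lower S-Exo values. Several members of this list are close paralogs that can share reads, here and in the other comparisons. They are not independent observations. Interferon-stimulated genes had 5 of 11 lower and 0 higher (median -0.94, percentile 2.24), with IFITM3 at 39.7 against 96.2 FPKM and CMPK2 at 0.359 against 2.76. Amino acid response genes had 4 of 6 lower and 1 higher (median -1.15, percentile 1.49), with PHGDH at 6.04 against 26.1. Of the BCR-ABL and bypass kinases, 4 of 8 were lower and 2 higher (median -0.98, percentile 2.59), and SYK had 4.33 FPKM in S-Exo and was listed at 0 in R-Exo. Drug metabolism and glutathione genes had 4 of 7 lower and 2 higher (median -1.05, percentile 3.41), with GSTM2 at 2.01 against 7.67. Histone genes had 2 of 9 higher and 0 lower (median 0.69, percentile 74.71), and ribosomal protein genes 0 of 5 higher and 1, RPL35A, lower (median -0.86, percentile 32.61). Exosome biogenesis and tetraspanin genes had 1 of 5 higher and 2 lower (median -0.87, percentile 21.96), with CD53 at 23.7 against 79.6 FPKM.

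ERK feedback genes had 2 of 11 higher and 1 lower (median 0.68) and TGF-beta, BMP and Wnt genes 3 of 9 higher and 1 lower (median 0.29), with LEF1 at 12.4 against 0.115 FPKM. BCL2 family genes had 1 of 5 higher and 2 lower (median -0.95), extracellular matrix genes 2 of 10 higher and 3 lower (median -0.79), and NF-kB and cytokine genes 1 of 7 higher and 2 lower (median -0.74). The glycolysis and hypoxia list had 0 of 6 higher and 1 lower (median -0.76). Megakaryocyte and platelet genes had 2 of 6 higher and 3 lower, with a median of -0.14 and a mean of 0.14. ABCB1 and ABCB4 were both higher, as were CD3D, CD22 and CD33. Of the other lists without a median, heat shock genes had 2 of 4 higher, cholesterol synthesis genes 2 of 4 and autophagy genes 3 of 4, each with 0 lower. STAT5 targets had 2 of 3 lower, the MHC list 1, PSMB9, of 3 lower and mast cell genes 1, KIT, of 2 lower, each with 0 higher. The cell cycle list had CDK6 higher and CDKN2D lower, the stem and progenitor list 1 higher and 2 lower of 4, and MT-ND3 differed by 0.17. Over 2154 compared genes, 499 were higher and 456 lower in R-Exo, with a median of 0.21. The higher share was 52.3% as deposited, 32.8% when re-scaled to a median of 0 and 46% after quantile normalization. Re-scaled, 5 cancer-testis antigen genes were higher and 3 lower (median 0.97), 0 histone genes were higher (median 0.47), TGF-beta, BMP and Wnt genes had 1 higher and 2 lower (median 0.07), and 3 ribosomal protein genes were lower (median -1.08). Re-scaled ERK feedback genes had 2 higher and 2 lower, the kinase list 1 and 5, drug metabolism genes 1 and 4, amino acid response genes 0 and 4, and exosome and tetraspanin genes 1 and 3. BCL2 family genes had 1 higher and 3 lower, interferon-stimulated genes 0 and 6, glycolysis and hypoxia genes 0 and 3, extracellular matrix genes 2 and 5, and autophagy genes 3 and 1. Heat shock and cholesterol synthesis genes had 1 higher each and 0 lower. The other lists kept their counts.

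**Figure D1:**
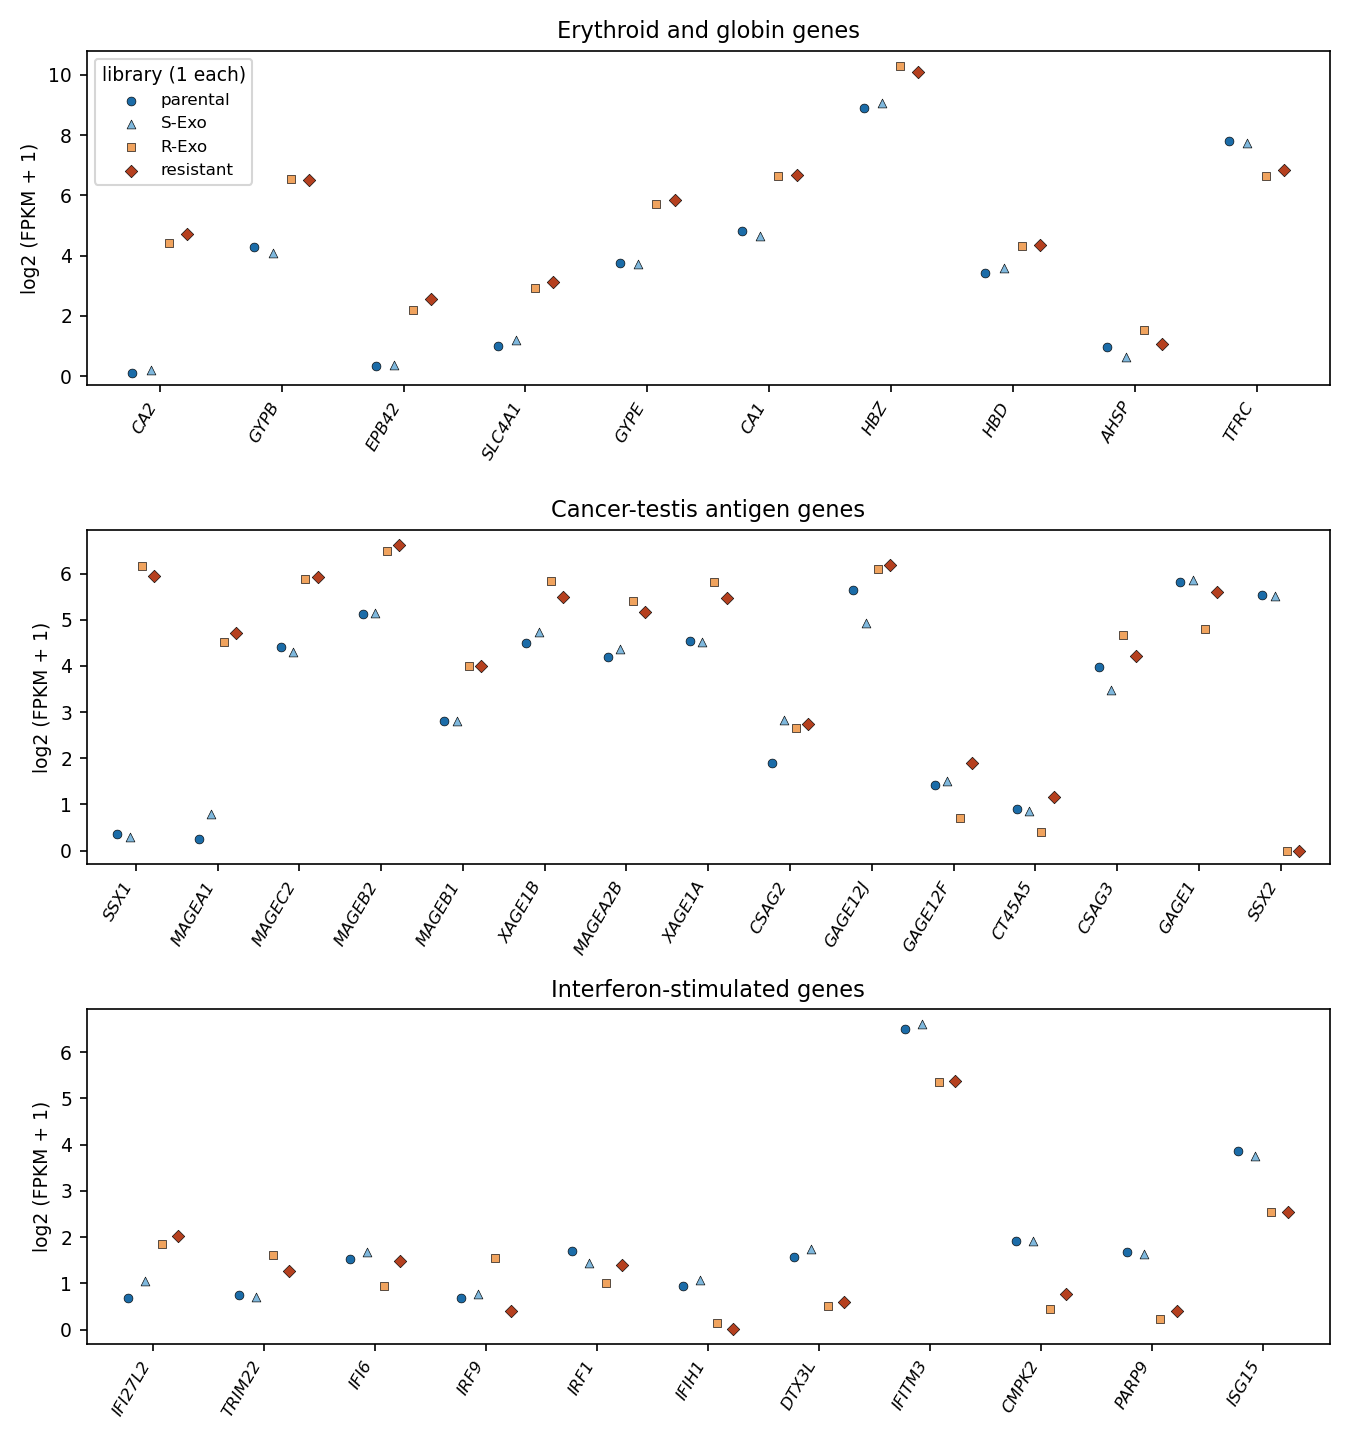
Expression of erythroid and globin, cancer-testis antigen and interferon-stimulated genes as log2 (FPKM + 1) on the vertical axis, with genes with at least 1 FPKM in one or more libraries along the horizontal axis and 1 point per library (10 genes of the erythroid and globin list are drawn). GYPB lies at 89.9 FPKM in resistant and 91.7 in R-Exo, against 18.4 in parental and 16.2 in S-Exo.

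The differences between R-Exo and S-Exo resembled those between resistant and parental cells. Across 2319 genes, Pearson's r between both sets of differences, which share no library, was 0.915 and Spearman's rho 0.882. Of these, 403 genes were higher in both, where independent lists of these sizes would share 129.5, and 276 were lower in both, against 76.69. Of the 682 genes past the size limit in both, 679 (99.56%, exact 95% interval 98.72 to 99.91) had the same direction. The authors' selection of differing genes enters these values. The 17 resistant-specific genes, such as CROT, CA2 and FKBP10, had a median of 101% of their resistant level in R-Exo, with a range from 0 to 144.6%, and a median of 0.193% in S-Exo. The 0 was that of INO80B-WBP1, a readthrough model, named after its value had been seen. Set directly against resistant cells, a comparison added after seeing the values, R-Exo had 30 genes higher and 23 lower of 1879 compared, with a standard deviation across genes of 0.41. MT-ND3 had 1196 FPKM in R-Exo against 579 in resistant and BEST1 12.3 against 2.35, while RPL37 had 42.0 against 21.5, a log2 difference of 0.93.

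**Figure D2:**
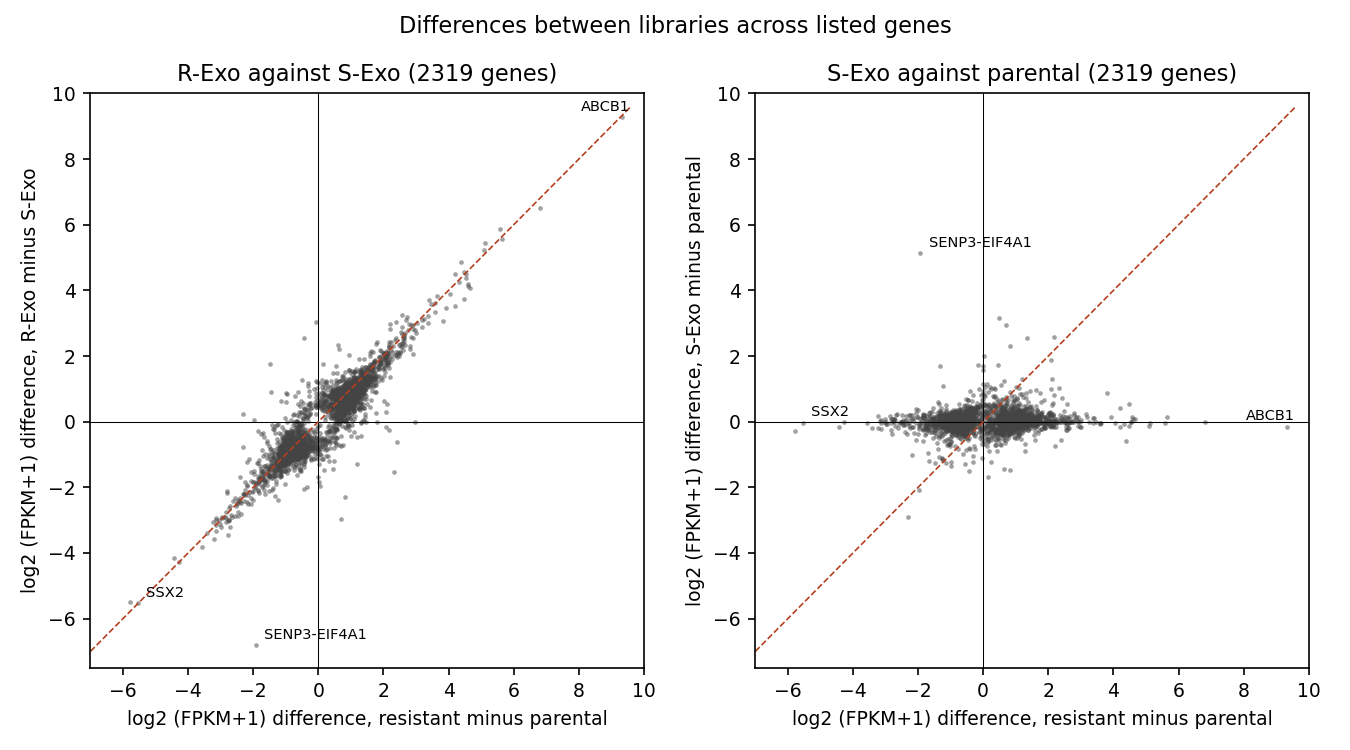
Each point is 1 of 2319 genes, with the log2 (FPKM + 1) difference of resistant minus parental on the horizontal axis and, on the vertical axis, R-Exo minus S-Exo (left) or S-Exo minus parental (right). The dashed line marks equal differences, and ABCB1 lies at 9.32 and 9.27 on the left.

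Set against parental cells, R-Exo again had ABCB1 as its highest gene (677 against 0.222 FPKM), with CROT, SSX1 and KIAA1324L also among the highest. The lowest were SSX2B, SSX2, SOHLH2, CBR1 and NMI. Of 2115 genes compared, 497 were higher and 454 lower, with a median of 0.34. The higher share was 52.3% as deposited, 26.9% re-scaled and 44.6% after quantile normalization. Erythroid and globin genes had 8 of 11 higher and 1 lower (median 1.85, percentile 99.99), cancer-testis antigen genes 8 of 14 higher and 2 lower (median 1.19, percentile 99.41) and interferon-stimulated genes 5 of 10 lower and 1 higher (median -0.87, percentile 2.45). The correlation of these differences with resistant/parental was 0.955. Unchanged libraries with equal errors, set against the 1 shared parental library, have a correlation of 0.5 by construction. The covariance was 1.51, against 0.0599 in 100 simulated draws of such libraries. Part of the correlation may come from the shared library. In both, 432 genes were higher and 319 lower, against 129 and 76.35 for independent lists.

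S-Exo differed from parental cells at few genes. Of 1723 compared, 28 were higher and 21 lower, with a median of 0.01 and a standard deviation across genes of 0.39, against 1.31 for resistant/parental. The highest were SENP3-EIF4A1 (165 against 3.71 FPKM), TOMM6, which encodes a part of the mitochondrial import pore (121 against 12.6), AL445685.3 (6.89 against 0.0309), 1 of the 2 MATR3 rows (79.9, a fold of 3.8) and SMIM11B (9.65 against 2.25). The lowest were SENP3 (8.02 against 27.9), TREX2 (3.83-fold lower than 5.74 in parental), BEST1 (2.94 against 8.37), NUDT4B (10.6 against 24.6) and EIF4A1, which encodes a translation initiation helicase (308 against 663). Of the 40 genes past the limit with a gene name, 31 (77.5%, exact 95% interval 61.55 to 89.16) had a coding model that shares exon sequence with another gene, against 187 of 1229 other named genes (15.22%, 13.25 to 17.35). Without the overlapping and unnamed genes, a choice made after seeing the data, 5 were higher and 4 lower.

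Of the gene lists, only the histone list had a member past the size limit in S-Exo against parental. That was HIST1H3F (4.40 against 1.65 FPKM), and the median of the 8 compared histone genes was 0.25, at percentile 99.78. The limit of poly-A libraries for histone genes, given above, holds here too. The medians of the erythroid (0.07), interferon-stimulated (0.10) and cancer-testis antigen (0.00) lists lay near 0. ABCB1 had 0.0985 FPKM in S-Exo and 0.222 in parental cells.

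Higher genes in resistant cells lay next to one another on chromosome 7. Among 15 neighbouring coding genes from KIAA1324L to STEAP1, 11 were higher, while the highest count in 1000 shuffles of the values over the listed genes was 9. For R-Exo against parental the top window ran from FZD1 to CDK6 on chromosome 7. It held 11 higher genes, with a highest count of 7 in the shuffles. A run of listed genes around ABCB1 with differences above 0.5 reached from GRM3 to CYP51A1, a span of 5.49 Mb from 86643914 to 92134803 on chromosome 7 in GENCODE release 29. The build behind the deposited values is not given in the sources used here. It held 21 listed of 26 annotated coding genes, with a median of 1.94 in resistant/parental, 1.99 in R-Exo/S-Exo and -0.06 in S-Exo/parental. The 12 genes from GRM3 to SRI, all listed, had a median of 3.99, with DMTF1 at 242 against 19.3 FPKM, DBF4 at 1013 against 44.6 and SRI, which encodes the calcium-binding protein sorcin, at 159 against 20.4. The 9 listed genes from STEAP1 to CYP51A1 had a median of 1.73. The run ended where a listed gene first failed to pass 0.5, and higher genes such as CDK6 lay beyond CYP51A1. Within 15 coding genes on either side of ABCB1, 17 of the 21 listed genes had a difference above 0 and 4 below, and CD36, at one end, was 4.29-fold lower in resistant cells.

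**Figure D3:**
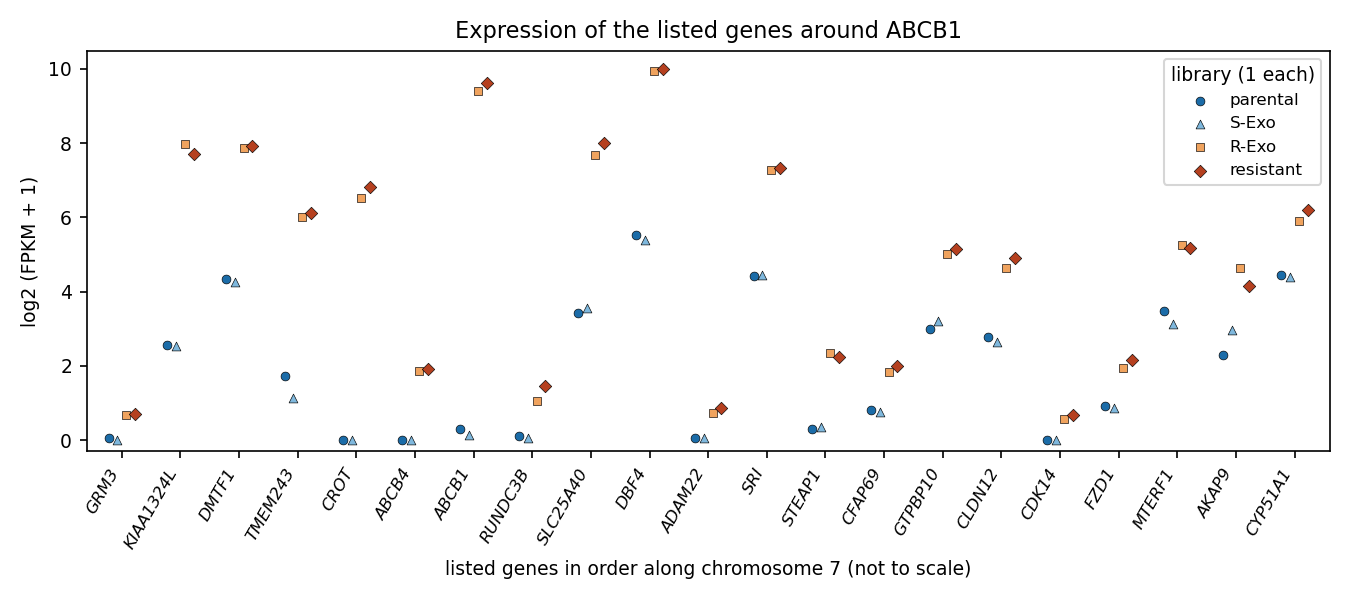
Expression as log2 (FPKM + 1) on the vertical axis of the 21 listed genes from GRM3 to CYP51A1, in their order along chromosome 7 (not to scale), with 1 point per library. DBF4 lies at 1013 FPKM in resistant and 975 in R-Exo, against 44.6 in parental and 40.7 in S-Exo.

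Lower genes lay together on chromosome 19, where 9 of 15 neighbouring coding genes from ZNF253 to ZNF493 were lower in resistant against parental and in R-Exo against S-Exo, with a highest count of 8 in 1000 shuffles in each. In R-Exo against parental the count was 8, with a highest of 7 in the shuffles. All of the listed genes in that window encode zinc finger proteins. ZNF93 had 0.730 FPKM in resistant and 0.742 in R-Exo, against 11.3 in parental and 12.2 in S-Exo. ZNF93, and the genes DMTF1, SRI and GRM3 above, were named after their values had been seen. Zinc finger genes are similar in sequence, so reads can be shared among them. Of all listed ZNF genes, 31 of 79 compared were lower and 3 higher in resistant cells (median -0.84), and 37 of 83 were lower and 2 higher in R-Exo against S-Exo (median -0.91). In S-Exo against parental, 0 were higher and 0 lower.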

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

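The alternatives were fixed before the data were examined, except the removal of overlapping and unnamed genes, which was chosen after seeing the data. With a pseudocount of 0.1, which enlarges the differences of low genes by construction, 908 genes were higher and 608 lower in resistant/parental, 776 and 758 in R-Exo/S-Exo, 769 and 738 in R-Exo/parental, and 81 and 45 in S-Exo/parental. With at least 5 FPKM, fewer genes were compared and the counts were 317 and 211, 254 and 246, 245 and 256, and 10 and 8 in the same order. Re-scaling to a median of 0 gave 276 higher and 755 lower in resistant/parental, 331 higher and 678 lower in R-Exo/S-Exo, and 279 higher and 759 lower in R-Exo/parental. Without overlapping or unnamed genes, 375 were higher and 262 lower in resistant/parental, 295 higher and 294 lower in R-Exo/S-Exo, 298 higher and 303 lower in R-Exo/parental, and 5 higher and 4 lower in S-Exo/parental, with fewer genes entering. Removing the filter could not change these counts, since a difference of 1 with a pseudocount of 1 needs a value of at least 1, so that setting shows nothing about them.

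The correlation of R-Exo/S-Exo with resistant/parental was 0.895 with a pseudocount of 0.1, 0.942 at 5 FPKM or more and 0.955 with the parental library as control, which is then shared. The genes higher in both numbered 667 with a pseudocount of 0.1 and 226 at 5 FPKM or more, and those lower in both 501 and 155. The share with the same direction was 98.649% with a pseudocount of 0.1. Resistant-specific genes taken from 1 FPKM had a median share of 0.8735 of their resistant level in R-Exo; the cause was not tested. Of 82 list medians under an alternative, 62 moved by less than the standard deviation of the S-Exo/parental differences and 20 by more. Those 20 include all 17 medians of resistant/parental under re-scaling, which subtracts 1 value from each gene, against 0 of 16 in R-Exo/S-Exo. The others were 2 medians in R-Exo/S-Exo with a pseudocount of 0.1, those of NF-kB (-1.17) and extracellular matrix genes (-1.63), and that of drug metabolism genes in resistant/parental at 5 FPKM or more (-1.04). Of all 82, 0 changed sign. With no replicates, a change of 0.01 in a correlation or 0.05 in that share was taken as a move. No paired analysis was possible because each group had 1 library, and leaving out a replicate was not possible for the same reason. The unknown depth leaves the counting error of every value open, most of all near 0.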

Other observations

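Whole chromosomes differed in their share of higher and lower genes. Of 46 compared genes on chromosome 14, 28 were higher and 4 lower in resistant cells (median 1.07), and in R-Exo against S-Exo 13 of 48 were higher and 5 lower (median 0.83). On chromosome 13, 21 of 56 were lower and 3 higher in resistant cells (median -0.86), although LCP1 on that chromosome had 55.5 against 0.654 FPKM, and in R-Exo against S-Exo 25 of 57 were lower and 2 higher (median -0.99). The X chromosome, on which the named cancer-testis antigen genes lie, had 27 of 69 genes higher and 11 lower in resistant cells (median 0.85). In R-Exo against S-Exo it had 28 of 66 higher and 9 lower (median 0.90). These chromosomes were picked after their values had been seen.

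The shuffle of values around ABCB1 and the share of overlapping gene models were set after a first look at the data but before their outcome had been viewed. The other tests below were chosen, or had their bounds revised, after the result was seen. The library labelled R-Exo lay close to the resistant line, with 30 genes higher and 23 lower of 1879, and covered a median of 94.44% of the parental-to-resistant distance over 528 genes, against 2.187% in S-Exo. The 9 genes with at least 5 FPKM in parental and at most 0.1 in resistant, among them CBR1, SYK and EREG, kept 0% of their summed parental level in R-Exo. That argues against RNA of resistant-cell vesicles added to RNA of parental cells, and against a mixture of resistant and parental cells with more than 5% parental cells. The spread of R-Exo/resistant differences was 1.03 times that of S-Exo/parental, as a library that holds RNA of resistant-line cells would give, so such cells are a candidate explanation. A full response of parental cells to the vesicles predicts the same values and cannot be told apart with 1 library and no DNA data.

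The genes beside ABCB1 were higher together in resistant cells and in R-Exo. Shuffled values gave at most 9 higher genes in a window, against 11, which argues against place in the list alone. Without ABCB1, its paralog ABCB4 and the overlapping RUNDC3B, the other 18 listed genes within 15 coding genes on either side, taken by position, had a median of 2.03 with 14 above 0 and 4 below, which argues against ABCB1 reads assigned to those genes as the whole cause. A segment present in more copies in the resistant line may account for higher neighbours of unrelated function, and 54.84% of all coding genes within 15 genes of ABCB1 were listed with a difference above 0. That share decides nothing, since genes outside the list have no value here and no DNA was measured, so more copies and shared regulation cannot be told apart.

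Of the 40 named genes past the size limit between S-Exo and parental, 77.5% had overlapping models, and of the 40 between R-Exo and resistant 80%; unnamed genes past the limit could not be placed and are left out. A different split of reads between overlapping models is a candidate explanation, and both MATR3 rows together had 173 FPKM in parental and 164 in S-Exo. The sum of SENP3, SENP3-EIF4A1 and EIF4A1 was 694 in parental and 481 in S-Exo. Because FPKM depends on model length, a re-split of reads can itself change such sums, so neither sum decides. The remaining 22.5% of named genes leave a response to vesicles of sensitive cells open. They were 9 genes, against 8 between R-Exo and resistant, and with 1 library each they cannot be told apart from differences between libraries.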
